A study of Mus musculus with 26 samples.

How the data were processed

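Polyadenylated RNA of mouse gastruloids was sequenced in 26 libraries that fall into 15 groups of genotype and hours after aggregation, and 8 of these groups hold 1 library. Genotype, stage and library name were taken from the sample labels. Per the labels' protocols most libraries were made with the ISML kit from Illumina, and replicates 2 and 3 of InvClone1 at 120h with the TruSeq Stranded mRNA kit. The short line names used here stand for the alleles that the labels give, and the meaning of i9-13 and of CBS in the allele names is not given in the sources used here.

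The deposited count table holds whole-number counts of reads per gene, not normalized, for 55141 genes. Per the submitters' processing notes, cutadapt 1.18, STAR 2.7.10a and Cufflinks 2.2.1 were used with the mouse build mm10. The counting program is named only by the name of the deposited table, as HTSeq, and its version, its strand setting and the annotation release are not given in the sources used here. Genes that overlap or lie antisense to each other, and genes with near-identical copies, are therefore uncertain where the counting could split or merge their reads. The authors also deposited FPKM values (fragments per kilobase of transcript per unit of sequencing depth) from Cufflinks for 55138 genes, in which the chromosome positions printed here are given. Gene names came from the deposited table, and 3 identifiers had no name. No genome was used, so GC content was not tested. Of the columns in the tables, 8 (4 in each) matched no sample and were not used.

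Total counts per library ran from 18746411 to 37716547 (median 22616412). With such totals 3 counts in a library, the limit that a count of 0 allows, correspond to 0.0778 to 0.165 CPM. Poisson intervals (exact, 95%), counting intervals of ratios and the floor of 3 counts cover counting error only, since reads without molecular identifiers are not independent molecules. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates of a group were compared by a chi-square test of their counts and differed by 16.0 to 222 per degree of freedom, far beyond sampling noise. This does not show that they came from separate cultures, and each library was counted as 1 sample.

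Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test with robust dispersion, TMM normalization, filter on expression with a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05). The 5 genotype comparisons, the HoxB tests and the check of the kit came from 1 fit of all 26 libraries with a term for group and a term for library name, over 17769 genes and with 8 residual degrees of freedom. A lone library in that fit is assumed to vary like the replicated groups. The stage comparison used the 10 ISML_second libraries of 5 lines, with line and stage as terms (15011 genes, 4 residual degrees of freedom). CPM values were counts scaled by the TMM-adjusted library size, and groups are given as mean ± SD. Fold changes are log2 with the standard error of the fit. The 10 HoxB genes were also adjusted alone, within each contrast.

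Gene lists numbered 23, with 354 entries, chosen from textbook markers before the data were examined, as were the design, the rule for named genes and the alternatives not marked as chosen later. They covered HoxB, its neighbours, the paralog groups of the other Hox clusters, tailbud, presomitic, somite, neural tube, neural crest, endoderm, notochord, endothelial, cardiac, intermediate mesoderm and pluripotency markers, heterochronic, imprinted, Y-linked, stress, hypoxia, proliferation, mitochondrial and histone genes. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. A list p without further words is the adjusted p at the preset correlation. Member counts are given over all genes tested and adjusted over the list alone.

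The genes named were the 10 HoxB genes in every comparison. Added to them, for Ins against Del, InsDel5to10 against Ins, InvClone1 against Ins and the stages, were the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with a mean of at least 1 CPM and no overlap between the groups (for the stages, the same direction in all 5 lines), leaving out predicted gene models. For the other comparisons 4 each way were taken. In each list with a member past the threshold up to 4 members with the smallest adjusted p were named. Some genes that this rule takes are not reported here. Other genes are said to have been chosen after their values were seen. A fold against a group at 0 counts was computed against 3 counts over the group, and ratios of 1 to 3 counts are given with their counting interval.

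Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, a minimum count of 50, no library term, a fit of the compared libraries alone without a library term, the replicate number as a block, limma on log2(FPKM + 1) for genes with a mean FPKM of at least 1, InvClone1 without its TruSeq libraries, and each replicate or line left out in turn. The stage comparison was also run without the line term, in the fit of all libraries and with the ISML_third pair of InvClone1 added. Between Ins and Del the deviations of same-numbered replicates from their group means correlated at 0.51, 0.26 and 0.64 across genes. Replicate 2 of Ins correlated more with replicate 1 of Del (0.297), and the replicates numbered 3 were the ISML_second libraries of both groups. For replicate 3 a pairing by number thus cannot be told apart from the library label. Replicates 1 and 2 of both groups were all ISML_first. Replicate 1 of Ins correlated with replicate 2 of Del at 0.0117, so crossed pairs lay both below and above same-numbered ones, and a pairing stays open. With the number as a block 2 genes passed. The test procedures were checked on simulated data with 200 changed genes per comparison. For edgeR, of 100 genes changed by 2-fold, 67 were recovered for Ins against Del, 13 for InsDel5to10 against Ins, 58 for InsDel7to10 against InsDel5to10, 41 for InvClone1 against Ins, 57 for the clones and 97 for the stages, and of 100 changed by 4-fold 98, 76, 95, 88, 94 and 100 in the same order. False calls made up 1.79% to 7.86% of edgeR calls, 12.9% to 18.5% of DESeq2 calls and 3.16% to 9.41% of limma calls. Apart from the changed genes, the simulated counts had a common mean per gene and independent noise. They held no effect of library label or line, so these rates do not cover such effects.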

Results

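Gastruloids are aggregates of mouse embryonic stem cells that elongate in culture and form tissues of the trunk and tail of the embryo. Polyadenylated RNA was sequenced from gastruloids of 8 lines that differ in edits of the HoxB cluster, a row of Hox genes that pattern the body axis. All lines carry HoxB Del/Del(i9-13), and the line with no further edit is called Del here. The Ins line carries Ins(CBS5-10) in addition. The lines InsDel5to10, InsDel7to10 and InsDel8to10 carry Ins(CBS5-10) followed by Del(CBS5-10), Del(CBS7-10) or Del(CBS8-10). InvClone1 and InvClone2 are both clones of Ins(CBS5-10):Inv(CBS5-10), and InvDel7to10 carries Inv(CBS5-10) with Del(CBS7-10). The title of the series names insulation of Hoxb13 by CTCF, a DNA-binding protein, as the subject of the study. At 120h after aggregation there were 4 libraries of InvClone1, 3 of Del, 3 of Ins, 2 each of InsDel5to10, InsDel7to10 and InvClone2, and 1 each of InsDel8to10 and InvDel7to10. At 144h there were 2 libraries of InvClone1 and 1 each of Del, Ins, InsDel8to10 and InvDel7to10, and InvClone1 also had 1 library at 96h and 1 at 168h. Of the 15 groups, 8 thus held 1 library and have no replicate check of their own. Total counts per library ran from 18746411 to 37716547.

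The labels also gave each library 1 of 4 library names, ISML_first, ISML_second, ISML_third and TruSeq_second, and marker genes differed with them. At 120h the mean of the 5 ISML_second libraries, which came from 5 lines, stood above that of the other 13 libraries in endoderm markers by 1.91 on the log2 scale (exact permutation test, two-sided, adjusted p = 0.00280). Their mean was also higher in notochord markers by 1.78 (adjusted p = 0.00105), endothelial and blood markers by 2.45 (0.00294), cardiac and lateral mesoderm markers by 1.52 (0.00158) and somite markers by 0.67 (0.00294). Of these 5 lists only the notochord values did not overlap between the 5 and the 13 libraries. Presomitic, neural tube, tailbud and pluripotency markers gave adjusted p of 0.284, 0.153, 0.853 and 0.853 in the same family of 9 lists. These permutation tests were chosen after the data were seen. They treat all libraries as interchangeable whatever their line, while InsDel8to10 and InvDel7to10 had their only 120h library under ISML_second. A pair of libraries stood apart in quality measures. Replicate 2 of InvClone1 at 144h had 0.0864% of its counts from mitochondrial genes, against 0.587% to 1.51% in the others. Replicate 2 of InvClone1 at 120h, a TruSeq library, had counts for 54.8% of the listed genes, against 37.5% to 43.4% in the others. Replicate 1 of InvClone1 at 120h differed from the other 3 libraries of its group by a chi-square per degree of freedom of 130.2 to 152, against 36.8 to 74.0 among those 3. Counts of genes were therefore also obtained without 6 libraries, called those that stood apart below. They were the 4 ISML_third libraries of InvClone1 and the pair with deviating quality measures. Of the ISML_third libraries only replicate 1 at 120h was shown to deviate by itself, and the others were left out with it for their line and label. That alternative was chosen after the data were seen.

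Hoxb13, the gene at the 5' end of the HoxB cluster whose product restrains axial extension, separated the genotypes at 120h. Its span in the deposited table is chromosome 11, 96194316 to 96197447 (mm10). In Del gastruloids it reached 62.2 ± 27.6 CPM (SD, n = 3). It was 0.809 ± 0.459 CPM in Ins (n = 3), 0.507 ± 0.349 in InvClone1 (n = 4) and 0.719 ± 0.0184 in InvClone2 (n = 2). In InsDel5to10 it was 28.6 ± 10.1 CPM (n = 2), and in InsDel7to10 it was 3.48 ± 1.75 CPM (n = 2). The single InsDel8to10 library had 0.622 CPM (95% Poisson interval 0.340 to 1.04, counting error only), and the single InvDel7to10 library had 5.08 CPM (4.16 to 6.14).

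**Figure D1:**
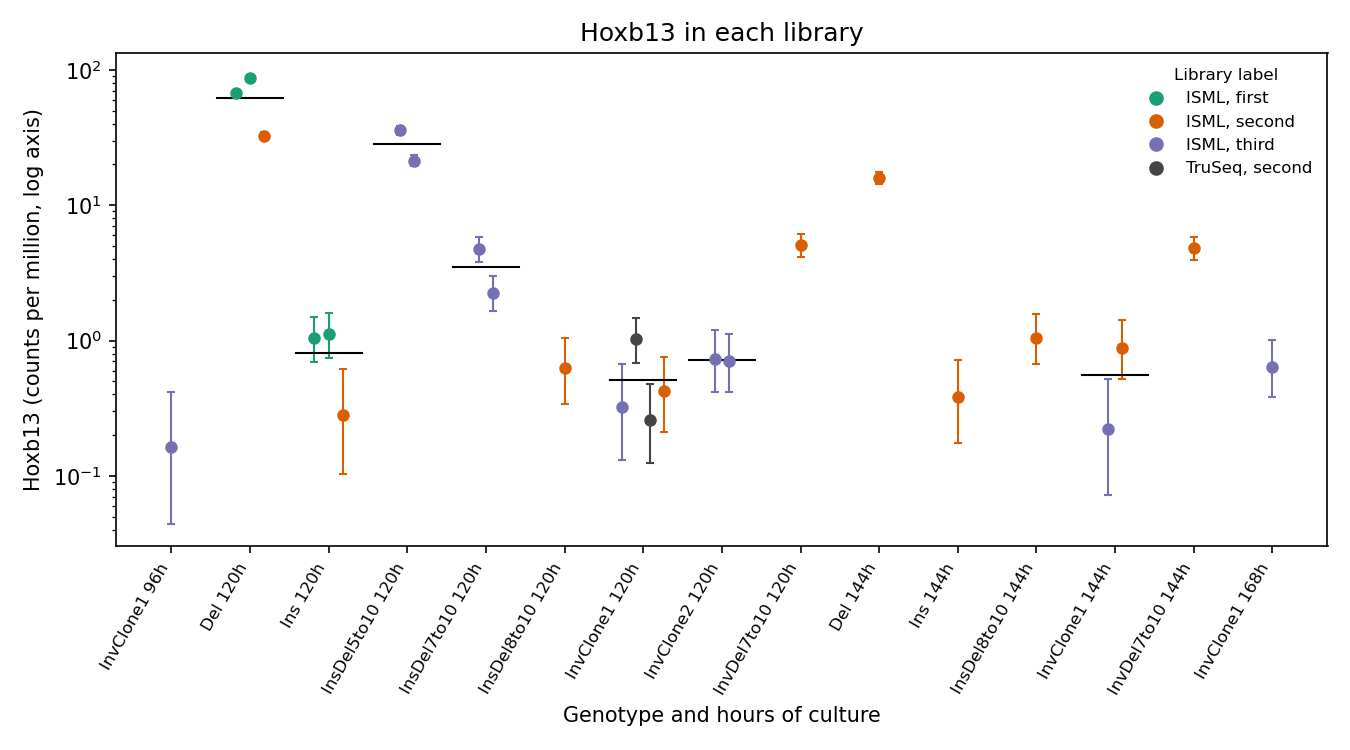
Hoxb13 in CPM, counts scaled by library size (log axis), in each library, by genotype and hours of culture. Points are libraries coloured by library label, bars are 95% Poisson intervals, and black lines are the means of groups with more than 1 library: the Del libraries at 120h sit between 32.5 and 87.0, the InsDel5to10 libraries at 21.4 and 35.7, and the Ins libraries between 0.281 and 1.11.

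Against Ins, Hoxb13 was higher by 6.30 ± 0.46 (log2 fold change ± SE) in Del, 7.42 ± 0.93 in InsDel5to10, 4.37 ± 0.94 in InsDel7to10 and 3.73 ± 0.64 in InvDel7to10 (edgeR, adjusted over the list alone, adjusted p = 8.59e-08, 3.36e-05, 0.00522 and 7.69e-04). InsDel8to10 lay at 0.71 ± 0.82, InvClone1 at 0.49 ± 0.79 and InvClone2 at 2.11 ± 0.99 relative to Ins, and none of these passed (adjusted p = 0.943, 0.968 and 0.434). Against Del, Hoxb13 was lower in Ins (-6.30 ± 0.46), InsDel8to10 (-5.59 ± 0.79), InvClone1 (-5.81 ± 0.74), InvClone2 (-4.19 ± 1.01) and InvDel7to10 (-2.57 ± 0.64), with adjusted p = 8.59e-08, 1.06e-04, 3.72e-05, 0.0126 and 0.0155 over the list alone. InsDel5to10 (1.11 ± 0.88) and InsDel7to10 (-1.93 ± 0.94) did not pass against Del (adjusted p = 0.544 and 0.174). Counting each genotype against Ins and against Del, 8 of 130 tests passed (Ins and Del counted once), 4 higher than Ins and 4 lower than Del, and all were of Hoxb13. In 3 of the 8 the line was InsDel8to10 or InvDel7to10, whose 1 library is assumed to vary like the replicated groups. Hoxb1 to Hoxb9, which lie 3' of it in the cluster, gave log2 fold changes between -0.62 (Hoxb3 in InvClone2 against Ins) and 1.30 (Hoxb6 in InsDel7to10 against Del), and none passed (lowest p adjusted over the list alone 0.134). Over all genes, Hoxb13 passed in Del against Ins, InsDel5to10 against Ins and InvClone1 against Del (adjusted p = 1.53e-04, 0.0299 and 0.0165).

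InsDel5to10, InsDel7to10 and InvClone2 share no library label with Ins or Del and are tied to them only through InvClone1. In the ISML_third libraries of InvClone1 Hoxb13 was near the floor, at 0.323 CPM at 120h and 0.222 CPM at 144h. That 120h library also stood apart from its group. The fitted folds of Hoxb13 moved with the library term. Without a library term InsDel5to10 was 5.11 ± 0.66 above Ins, InsDel7to10 was 2.07 ± 0.64 above Ins (adjusted p = 0.0549, no longer past the threshold) and InsDel7to10 lay -4.16 ± 0.71 from Del (adjusted p = 3.42e-04, now past it). The sign of 4 fitted differences turned, so their direction is not settled. InsDel5to10 lay -1.12 ± 0.60 from Del, and InsDel8to10, InvClone1 and InvClone2 lay -0.40 ± 0.92, -0.70 ± 0.59 and -0.19 ± 0.70 from Ins, with means below that of Ins, and none passed (adjusted p = 0.271, 0.942, 0.321 and 0.835). Without the term Hoxb3 passed too, lower than Ins in InsDel5to10 (-0.86 ± 0.26, adjusted over the list alone, adjusted p = 0.0239) and in InvClone2 (-0.89 ± 0.26, 0.0368). For InsDel7to10 the p over all alternatives ran from 2.81e-06 to 0.0549 against Ins and from 1.50e-04 to 0.159 against Del. Within the ISML_second libraries alone, 1 per line, Del stood 6.48 above Ins, InvDel7to10 3.82, InsDel8to10 0.95 and InvClone1 0.48. Within the ISML_third libraries, InsDel5to10 was 5.30 ± 0.55 and InsDel7to10 2.26 ± 0.54 above InvClone2 (adjusted over the list alone, adjusted p = 4.34e-06 and 0.0122), a reference chosen after the data were seen.

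Ins and Del were compared to ask what the inserted segment changes. Hoxb13 fell by 6.30 on the log2 scale and was the 1 gene of 17769 that passed (edgeR adjusted p = 1.53e-04), lower in all 3 Ins libraries than in any Del library. At an unadjusted p under 0.05 there were 188 genes. The other HoxB genes were level, from -0.05 ± 0.24 for Hoxb4 to 0.33 ± 0.30 for Hoxb6. Among the HoxB genes the median log2 fold change was 0.13 and the mean -0.51, since Hoxb13 alone was low. Endoderm markers, such as the epithelial keratin Krt8 at 14.0 ± 13.2 against 22.9 ± 13.5 CPM, had a median of -1.04 and 0 of 18 passed, over all genes or adjusted over the list alone (camera adjusted p = 4.85e-10; adjusted p = 0.661 with an estimated correlation). Lower medians of hypoxia (-0.30, adjusted p = 6.21e-04), endothelial and blood (-0.92, adjusted p = 0.00741) and intermediate mesoderm genes (-0.53, adjusted p = 0.00953) and higher ones of tailbud (0.23, adjusted p = 6.21e-04) and presomitic genes (0.19, adjusted p = 7.91e-04) likewise had no member past the threshold over all genes. With an estimated correlation their adjusted p ran from 0.661 to 0.732. Adjusted over the list alone, 1 of 6 intermediate mesoderm genes was lower and 0 of the others passed. The cardiac and mitochondrial lists had positive medians (0.18 and 0.13) and tests that pointed down, the pluripotency list (-0.15) was negative with a test that pointed up, and the imprinted and immediate early lists had medians and means of opposite sign (adjusted p = 0.864 each).

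A fit of the 6 Ins and Del libraries alone, which also dropped the library term, left Hoxb13 at -6.21 with adjusted p = 0.102, outside the threshold, while over all the alternatives its adjusted p ran from 2.99e-89 to 0.102. In that fit edgeR called 0 genes (82 at an unadjusted p under 0.05), and DESeq2 and limma in the fit of all libraries called 1 each. With the replicate number as a block the count of genes was 2 instead of 1.

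InsDel5to10 against Ins asked what deleting CBS5-10 again changes. Hoxb13 rose by 7.42 ± 0.93 on the log2 scale (edgeR adjusted p = 0.0299), with means of 28.6 and 0.809 CPM, a ratio of 35.3 between the means. The fitted value is larger because the groups share no library label. The predicted gene Gm10736, named after its values were seen, was the other of the 2 genes that passed (1.68 ± 0.21, adjusted p = 0.0299), with means of 69.8 ± 4.57 and 69.9 ± 18.2 CPM. At an unadjusted p under 0.05 there were 2768 genes. The other HoxB genes did not pass and ran from -0.58 ± 0.38 for Hoxb3 to 0.74 ± 0.45 for Hoxb4. Their direction depends on the library term: without it all 9 lay below Ins, from -1.14 ± 0.48 for Hoxb2 to -0.0674 ± 0.47 for Hoxb9, and none passed over all genes. In the 5 libraries alone without that term Hoxb2 (-1.12 ± 0.16, adjusted p = 0.0169) and Hoxb3 (-0.84 ± 0.14, 0.0267) passed, and with the replicate number as a block Hoxb2, Hoxb3 and Hoxb6 (-1.15, -0.88 and -1.26; adjusted p = 0.00331, 0.00424 and 0.0337). Neighbours of HoxB (median 0.37), tailbud (0.82), presomitic (0.72) and hypoxia genes (0.85) had higher medians and mitochondrially encoded genes a lower one (-1.43), all with camera adjusted p = 0.00918 and no member past the threshold over all genes. Each had adjusted p = 0.875 with an estimated correlation. Adjusted over the list alone 1 of 26 neighbours of HoxB was higher and 0 of the members of the other 4 lists passed. The median (0.76) and mean (-0.12) of the Y-linked list differed in sign, as did those of the pluripotency list (-0.10 and 0.30; adjusted p = 0.672 and 0.481).

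Leaving out any 1 of the 5 compared libraries ended the Hoxb13 call, with log2 fold changes of 7.003 to 7.73 and adjusted p of 0.0629 to 0.536, against a range of 1.41e-28 to 0.536 over all alternatives. The edgeR count of genes was 0 or 1 in those fits (1284 to 2858 at an unadjusted p under 0.05), 2 with limma, 385 with DESeq2, 841 with no filter, 633 in a fit of the 5 libraries alone without a library term, and 21 without the 6 libraries that stood apart and without a library term.

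InsDel7to10 against InsDel5to10 set Del(CBS7-10) against Del(CBS5-10) of the inserted segment, in 4 ISML_third libraries. Hoxb13 fell by 3.04 ± 0.48 on the log2 scale, from 28.6 to 3.48 CPM (edgeR adjusted p = 0.0246). Scx, a transcription factor of tendon progenitors, rose by 3.13 ± 0.57 (adjusted p = 0.0431) and Heyl, a Notch target, by 2.50 ± 0.35 (0.0121). Cxcl12, a chemokine, rose by 2.07 ± 0.35 (0.0440) and Fmod, a collagen-binding proteoglycan of connective tissue, by 1.90 ± 0.30 (0.0216). The 16 named genes other than Hoxb13 include Hoxb1 to Hoxb9, which did not pass here and so had no call to lose. Of the 16, 4 lost the threshold in a fit of the 4 libraries alone without a library term. With the replicate block 4 lost it too, and 3 did so without a library term in the fit of all libraries. The Y-linked genes were at background in InsDel7to10: Ddx3y had 0 counts against 3233, at least 976-fold lower, Uty had 0 against 1672, at least 505-fold lower, and Eif2s3y had 1 against 1702, a ratio of 1541 with a 95% counting interval of 276 to 60900.5. These bounds set 3 counts over the group. Of the 5 genes of the list of Y-linked genes and Xist, 3 fell over all genes and 4 adjusted over the list alone, with a median of -10.31 as fitted and -8.98 with genes at 0 set to their bound (camera adjusted p = 3.01e-16; adjusted p = 0.00545 with an estimated correlation).

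In total 45 genes passed in this comparison, 23 higher and 22 lower, and most lay in a few chromosome segments. Of the 23 higher genes 15 lay on chromosome 3 between 90 and 120 Mb (mm10), where 0.396 would fall if calls were spread evenly over the genes tested. They included the proteasome subunit genes Psmb4 (0.86 ± 0.16) and Psmd4 (0.77 ± 0.13) and Arnt, which encodes a partner of hypoxia-inducible factors, (0.68 ± 0.11). Of the 22 lower genes 13 lay on the X beyond 160 Mb, where 0.0520 would fall, and 4 on the Y. The X-linked ones included Rbbp7, a histone chaperone gene (-1.10 ± 0.14), Piga, which acts in GPI anchor synthesis (-1.16 ± 0.14), and Fancb, a DNA repair gene (-1.44 ± 0.17). The genes of these segments were singled out after their values were seen. Outside the segments and the Y, 8 genes were higher and 5 lower. Besides the named ones these were Islr, Chst15, Serf1 and H1f0, which were higher, and Nt5e, Frem2, Nav2 and Miip, which were lower.

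**Figure D2:**
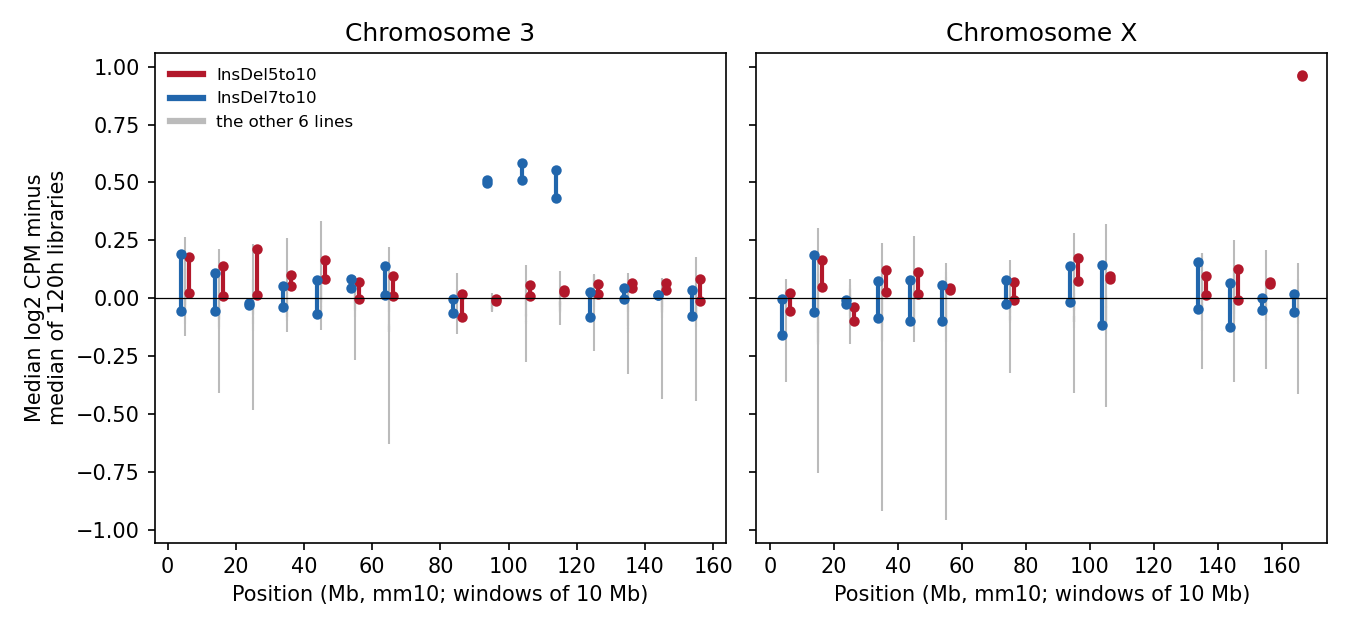
Median log2 CPM of the genes in windows of 10 Mb along chromosomes 3 and X, minus the median of the 120h libraries, by position in mm10. Coloured points are the lowest and highest library of InsDel5to10 and InsDel7to10 joined by a line, and grey lines span the libraries of the other 6 lines at all stages: InsDel7to10 sits between 0.43 and 0.58 in the windows from 90 to 120 Mb of chromosome 3, and InsDel5to10 at 0.96 beyond 160 Mb on the X.

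Marker lists of other tissues differed between these 2 lines too. Endoderm markers had a median of -2.56 in InsDel7to10, and 0 of 18 passed over all genes but 12 were lower adjusted over the list alone (camera adjusted p = 7.08e-13; adjusted p = 0.495 with an estimated correlation). Among the 12, chosen after their values were seen, were the epithelial adhesion gene Epcam (6.56 against 27.6 CPM, -2.08 ± 0.53) and the desmosome gene Dsp (61.5 against 166 CPM, -1.43 ± 0.35). Somite markers had a median of 0.78, with 0 of 16 past the threshold over all genes and 8 higher adjusted over the list alone (adjusted p = 9.24e-07; adjusted p = 0.497 with an estimated correlation). They included the sclerotome genes Pax1 (36.5 against 3.60 CPM, 3.33 ± 0.92) and Uncx (64.7 against 11.9 CPM, 2.43 ± 0.55). Pluripotency and germ cell markers had a median of -3.70 (adjusted p = 1.05e-04), with 1 higher and 3 lower of 19 adjusted over the list alone, and notochord markers a median of -2.09 (adjusted p = 0.0242), with 0 of 6. Presomitic genes had a median of 0.73 (adjusted p = 0.00467), hypoxia genes of -0.45 (adjusted p = 0.00621) and histone genes of 1.10 (adjusted p = 0.0112), with 1 of 17, 0 of 14 and 0 of 14 past the threshold adjusted over the list alone and 0 over all genes. With an estimated correlation the adjusted p of these 5 lists was 0.701. By library, the medians of the somite, pluripotency, hypoxia and histone lists overlapped between the lines, and those of the endoderm, presomitic and notochord lists did not. Relative to the mean of the 120h libraries, somite medians were 0.50 and -0.29 in InsDel7to10 and -0.79 and -0.20 in InsDel5to10. Pluripotency medians were -1.12 and -2.39 in InsDel7to10 and -1.69 and 1.65 in InsDel5to10. The HoxB list had a median of 0.31, a mean of -0.05 and a test that pointed up (adjusted p = 0.595).

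**Figure D3:**
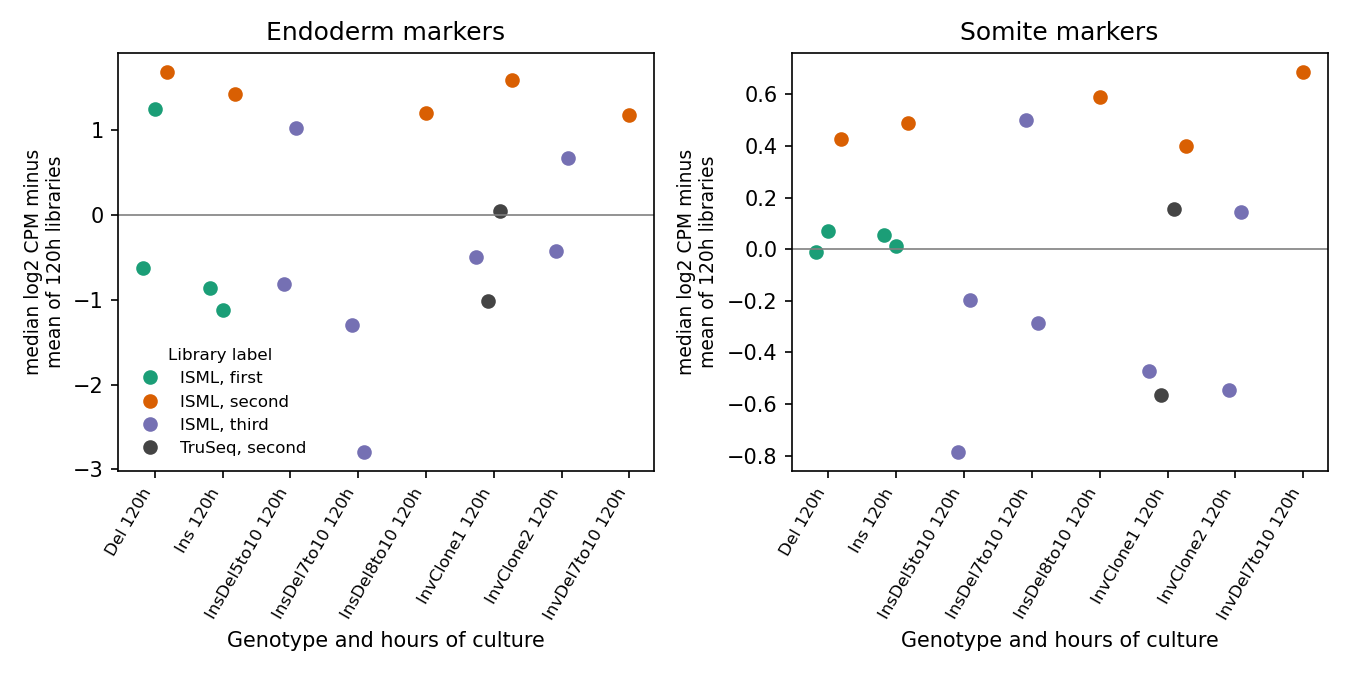
Median log2 CPM of endoderm markers (left) and somite markers (right) in each 120h library, minus the mean of the 120h libraries, by genotype and coloured by library label. Each point is 1 library: endoderm medians of the ISML_second libraries lie between 1.1795 and 1.68 and those of InsDel7to10 at -2.80 and -1.29.

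The count of 45 was 3, 12, 7 and 939 when replicate 1 or 2 of InsDel5to10 or replicate 1 or 2 of InsDel7to10 was left out, 7 without a library term, 4 in a fit of the 4 libraries alone without that term, 292 with DESeq2, 957 with no filter, and 26 without the 6 libraries that stood apart and without a library term. The Hoxb13 call ended without replicate 1 of InsDel5to10 (-2.63, adjusted p = 0.114), without replicate 1 of InsDel7to10 (-3.66, 0.0588), without a library term (-3.04, 0.258) and in a fit of the 4 libraries (-3.02, 0.442), and its adjusted p over all alternatives ran from 3.97e-19 to 0.442.

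InvClone1 against Ins asked what turning the segment round changes. Hoxb13 stayed low in both, at 0.507 ± 0.349 and 0.809 ± 0.459 CPM, and did not differ beyond its error (0.49 ± 0.79). The interval of that difference, -1.06 to 2.04, leaves room for a change of either sign. The 3 genes that passed were Y-linked: the RNA helicase gene Ddx3y (3 counts against 3638, a ratio of 1842 with a 95% counting interval of 629.7 to 8934), the histone demethylase gene Uty (3 against 1588, 804 with 275 to 3902) and Eif2s3y, which encodes a translation initiation factor (0 against 1328, at least 672-fold lower). Their edgeR adjusted p were 7.37e-04, 0.00138 and 9.53e-04, and 169 genes had an unadjusted p under 0.05. Kdm5d, at 2 against 8 counts, had a ratio of 6.07 (1.21 to 58.7). Of that list, which holds Xist too, 3 of 5 genes fell over all genes and 4 adjusted over the list alone, with a median of -12.00 as fitted and -9.39 with genes at 0 set to their bound (camera adjusted p = 1.59e-39; adjusted p = 2.16e-04 with an estimated correlation). The HoxB genes gave log2 fold changes from -0.40 ± 0.30 for Hoxb3 to 0.49 ± 0.79 for Hoxb13. Mitochondrially encoded genes had a lower median (-0.54, adjusted p = 0.00733), and histone genes (0.46, adjusted p = 0.0245) and neighbours of HoxB (0.08, adjusted p = 0.0298) higher ones, with no member past the threshold over all genes or adjusted over the list alone. With an estimated correlation their adjusted p was 0.972, 0.972 and 0.669. Median, mean and test differed in sign for the neural tube, neural crest, notochord and cardiac lists, none of which passed.

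Without replicate 4 of InvClone1, the 1 library of this group that shares a label with Ins, 303 genes passed, 60 higher and 243 lower, and none of the 3 Y-linked genes was among them. Their fitted log2 fold changes were -13.27 for Ddx3y, -12.08 for Uty and -12.00 for Eif2s3y (adjusted p = 1 each, with no standard error), so the calls ended while the differences stayed as large. With the replicate number as a block these calls ended too (-10.30, -9.10 and -11.92; adjusted p = 0.134, 0.179 and 0.242).

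InvClone2 and InvClone1 are clones of 1 genotype. Hoxb13 was low in both (0.719 ± 0.0184 and 0.507 ± 0.349 CPM) and did not pass (1.62 ± 0.80, adjusted p = 0.205), nor did any other HoxB gene. In the fit with a library term 2071 of 17769 genes passed, 1556 higher and 515 lower in InvClone2. Of them 992 differed by at least 2-fold, 960 higher and 32 lower. Among the genes with the largest differences on the higher side were the ribosomal protein genes Rps29 at 333 ± 27.5 against 144 ± 64.3 CPM (2.51 ± 0.48) and Rpl18 at 875 ± 75.8 against 550 ± 278 CPM (2.31 ± 0.36). Rpl18-ps2 (3.68 ± 0.55) is a pseudogene that can share reads with Rpl18, so its value is uncertain. Rtl8c, derived from a retrotransposon, was higher by 2.35 ± 0.34. On the lower side stood Wapl, which releases cohesin from DNA (125 ± 1.67 against 199 ± 54.6 CPM, -1.19 ± 0.12), the zinc finger gene Zfp273 (-1.40 ± 0.39) and Kbtbd3 (-1.14 ± 0.35). These 7 genes had edgeR adjusted p from 0.00172 to 0.0492. Set against replicate 1 of InvClone1, which has the ISML_third label of InvClone2, the 2071 genes differed by a median of 0.96 in the called direction, and against its replicates 2, 3 and 4 by -0.07, -0.02 and -0.06.

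Some list members that passed between the clones had nearly the same mean CPM in both groups, so their fold changes rest on the library term. Cdk5rap3, a neighbour of HoxB, was fitted at 0.91 ± 0.13 with means of 56.8 and 57.0 CPM, and Scrn2, another neighbour, at 2.39 ± 0.39 with 18.5 and 16.7 CPM. The same held for the DNA replication gene Mcm2 (416 and 406 CPM, 0.57 ± 0.16) and the imprinted gene Ndn (125 and 115 CPM, 1.07 ± 0.23), while the Notch receptor gene Notch1 stood at 391 and 316 CPM (1.08 ± 0.32). Hoxa2 (19.5 and 29.6 CPM, -0.75 ± 0.21), the mitotic checkpoint gene Bub1 (191 and 236 CPM, -0.70 ± 0.13) and the activin receptor gene Acvr2b (105 and 76.4 CPM, 1.06 ± 0.21) did not overlap between the groups. Wnt5b (1.04 ± 0.28), Cited1 (1.53 ± 0.44) and Dlk1 (1.66 ± 0.43) also passed, as did Osr2, Nkx3-2, Nkx6-2, Myl7 and H4c4 at means of 2.04 CPM or lower. Neighbours of HoxB (2 of 26 over all genes, 4 adjusted over the list alone), tailbud (1 of 18 and 1) and presomitic genes (2 of 17 and 2) had higher medians of 0.55, 0.80 and 0.90 (camera adjusted p = 0.0413 each; adjusted p = 0.976 each with an estimated correlation). Median, mean and test differed in sign for the endothelial, imprinted, heterochronic and Y-linked lists and for paralog groups 1 to 9, none of which passed.

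The count fell to 0 without a library term (389 genes at an unadjusted p under 0.05), in a fit of the 6 libraries alone, also without that term (168) and without the 6 libraries that stood apart and without a library term (841), while DESeq2 with the term gave 2872 and limma 2492. Left out 1 at a time, replicate 1 of InvClone1 gave 1166 genes, of which 444 were among the 2071, and replicates 1 and 2 of InvClone2 gave 792 and 617.

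From 120h to 144h most measured genes of the neural tube and posterior Hox lists rose, and most of the presomitic and tailbud lists fell. These were 5 lines with 1 ISML_second library at each stage. The tests of these 4 lists passed at the preset correlation and not with an estimated one (adjusted p = 0.135 to 0.410). Sst, which encodes somatostatin, was at 1 count in the 120h libraries and 264 at 144h (a ratio of 282 with a 95% counting interval of 50.2 to 11175), and the glycine receptor gene Glra1 at 2 and 322 (172, 47.2 to 1426). The neuronal transcription factor genes Myt1 (6.29 ± 0.39), Nhlh1 (6.09 ± 0.40), Lhx3 (5.72 ± 0.47) and Neurod4 (5.56 ± 0.29) rose, as did Dcx, a microtubule gene of young neurons (5.55 ± 0.36), and Ghrl, which encodes ghrelin (5.73 ± 0.42). Msgn1 fell by 3.76 ± 0.49, Tbx6 by 3.52 ± 0.46, Ripply2 by 3.49 ± 0.36 and Mesp2 by 2.86 ± 0.32, all transcriptional regulators of presomitic mesoderm and segmentation. Adgrd1 (-3.20 ± 0.19), Pglyrp3 (-2.97 ± 0.40), Npbwr1 (-2.87 ± 0.27) and Cer1, a secreted BMP and Nodal antagonist (-2.83 ± 0.28), also fell. These 16 genes had edgeR adjusted p from 4.50e-05 to 0.00207. By the rule that named them, each moved the same way in all 5 lines of this comparison. In the ISML_third pair of InvClone1, which is not part of it, Ghrl did not rise (5 counts at 120h and 1 at 144h). Sst stood there at 0 CPM at 120h and 0.0444 CPM at 144h, too low to show its rise.

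In total 2280 of 15011 genes passed between the stages, 1388 higher and 892 lower at 144h, and 891 of them differed by at least 2-fold (606 higher, 285 lower).

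Within HoxB, Hoxb1 fell by 1.04 ± 0.16, from 39.9 ± 2.63 to 19.98 ± 5.69 CPM (n = 5, adjusted p = 0.00363). Hoxb6 (0.93 ± 0.10), Hoxb7 (0.56 ± 0.15), Hoxb5 (0.49 ± 0.12) and Hoxb9 (0.41 ± 0.08) rose, with adjusted p of 8.58e-04, 0.0403, 0.0326 and 0.0125. Thus 4 HoxB genes were higher and 1 lower over all genes, and 4 and 3 adjusted over the list alone. Their median was -0.10, their mean 0.03 and the test of the list pointed up (adjusted p = 0.825). Hoxb13 lay at -0.11 ± 0.31 and did not pass, with 32.5 CPM at 120h and 16.0 at 144h in Del and 5.08 CPM or lower in the 4 other lines at both stages. Among the genes of the other clusters, Hoxa10 (2.04 ± 0.20), Hoxc10 (2.30 ± 0.23), Hoxa11 (4.24 ± 0.49) and Hoxd10 (2.61 ± 0.49) rose, and these were all 4 measured members of paralog groups 10 to 13 (camera adjusted p = 8.53e-05; adjusted p = 0.410 with an estimated correlation). Of the 18 genes of paralog groups 1 to 9, 8 rose and 3 fell over all genes, and 9 and 3 adjusted over the list alone (adjusted p = 0.199). Hoxc9 (1.17 ± 0.12), Hoxc6 (0.89 ± 0.10) and Hoxa6 (1.21 ± 0.14) were among those that rose.

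Of 21 neural tube genes 20 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 2.16 (camera adjusted p = 6.82e-21; adjusted p = 0.135 with an estimated correlation). Sox2 rose from 74.3 ± 11.4 to 224 ± 49.6 CPM (1.58 ± 0.09), the neural progenitor genes Sox1 by 1.92 ± 0.09 and Pax6 by 2.98 ± 0.15, and the neuronal RNA-binding protein gene Elavl3 by 4.25 ± 0.21. Of 17 presomitic and segmentation genes 14 fell over all genes and 17 adjusted over the list alone, with a median of -1.39 (adjusted p = 8.23e-15; adjusted p = 0.135 with an estimated correlation). The Notch ligand genes Dll3 (-1.92 ± 0.13) and Dll1 (-1.03 ± 0.07) and the segmentation gene Ripply1 (-1.93 ± 0.15) were among them. Of 18 tailbud and neuromesodermal progenitor genes 1 rose and 14 fell over all genes, and 2 and 14 adjusted over the list alone, with a median of -1.46 (adjusted p = 1.20e-07; adjusted p = 0.410 with an estimated correlation). T, the Brachyury gene, fell from 70.0 ± 11.2 to 20.8 ± 11.6 CPM (-1.89 ± 0.22), and the signalling genes Fgf8 (-1.64 ± 0.15) and Rspo3 (-1.37 ± 0.15) and the retinoic acid-degrading enzyme gene Cyp26a1 (-1.55 ± 0.20) also fell. Of 16 somite genes 2 rose and 8 fell over all genes, and 3 and 10 adjusted over the list alone, with a median of -0.77 (adjusted p = 0.00265; adjusted p = 0.410 with an estimated correlation). Meox1 (-1.07 ± 0.09), Foxc2 (-1.27 ± 0.08), Foxc1 (-0.83 ± 0.08) and Tbx18 (-1.17 ± 0.11) were among those that fell.

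**Figure D4:**
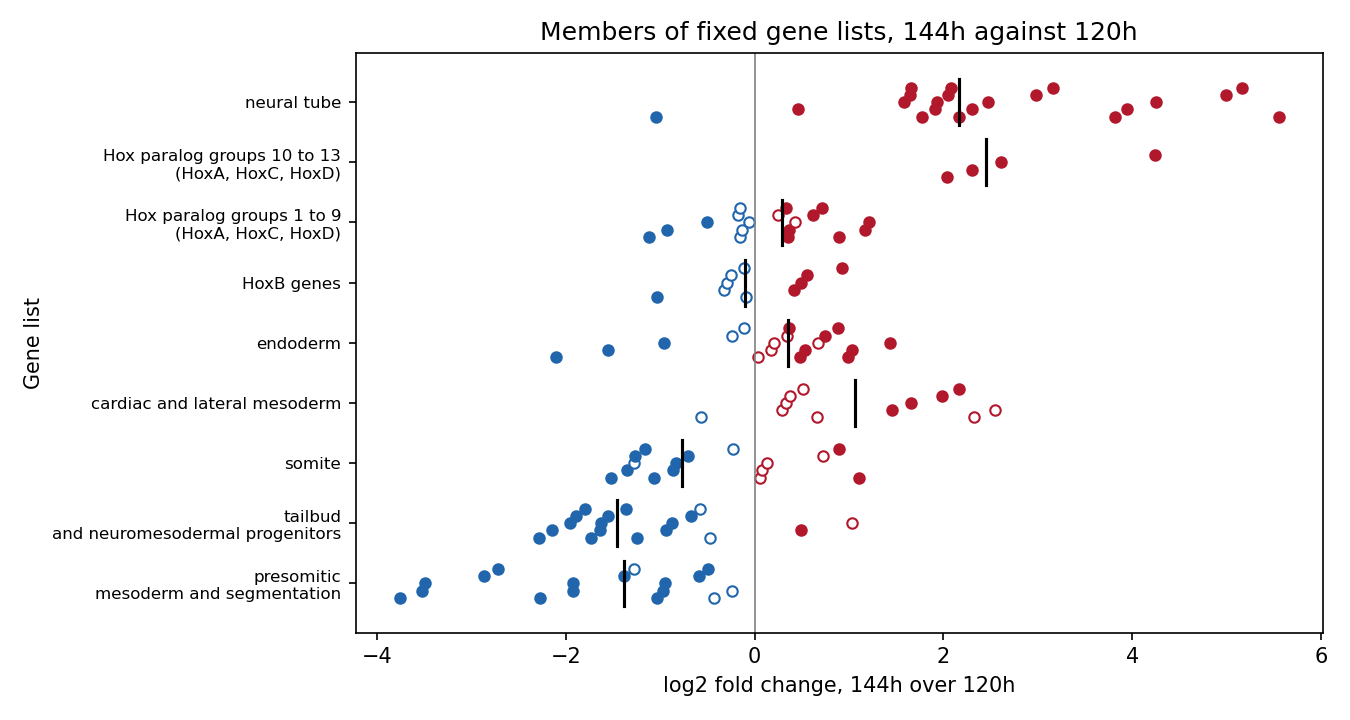
Log2 fold change from 120h to 144h (horizontal axis) of the members of 9 gene lists (vertical axis). Each circle is a gene, filled where its adjusted p was under 0.05 and open otherwise, red above and blue below 0, and black lines are list medians: neural tube genes have a median of 2.16 and presomitic genes of -1.39.

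Other lists moved less uniformly. Of 12 cardiac and lateral mesoderm genes 4 rose over all genes, and 6 rose and 1 fell adjusted over the list alone, with a median of 1.06 (adjusted p = 0.00303; adjusted p = 0.410 with an estimated correlation). They were the transcription factor genes Gata4 (2.17 ± 0.14), Isl1 (1.46 ± 0.22), Tbx20 (1.65 ± 0.36) and Hand2 (1.99 ± 0.50). Endoderm genes went both ways, 8 of 18 up and 3 down over all genes and 9 and 3 adjusted over the list alone (adjusted p = 0.0689). Among them the epithelial genes Krt8 (1.04 ± 0.13) and Cldn4 (0.74 ± 0.13) rose, and Sox17 (-0.96 ± 0.16) and Spink1 (-2.11 ± 0.37) fell. In the endothelial and blood list Pecam1 rose by 1.67 ± 0.15, while Etv2 (-1.64 ± 0.23), Tek (-1.22 ± 0.22) and Tal1 (-1.15 ± 0.27), which act early in that lineage, fell. There 1 of 12 rose and 4 fell over all genes, and 1 and 5 adjusted over the list alone (adjusted p = 0.505). Intermediate mesoderm lost Lhx1 (-2.10 ± 0.26) and Wt1 (-1.199 ± 0.18), 2 of 5 by either adjustment, with a median of 0.04 and a test that pointed down (adjusted p = 0.158). The neural crest genes Sox9 (1.32 ± 0.10) and Ngfr (0.44 ± 0.12) rose, among 3 of 6 that did by either adjustment (adjusted p = 0.0825). The notochord genes Shh (0.68 ± 0.16), Foxj1 (0.91 ± 0.24) and Krt7 (0.89 ± 0.24) rose, 3 of 5 by either adjustment (adjusted p = 0.155).

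Timing genes of the Lin28 and let-7 pathway, which acts in the heterochronic control of development, changed little. Lin28a, which blocks let-7 maturation, fell by 0.39 ± 0.09 and Arid3a by 0.48 ± 0.07, while Gdf11, a signal for the trunk-to-tail transition, rose by 0.31 ± 0.07 and Igf2bp2 by 0.21 ± 0.06. Over all genes 2 of 11 rose and 2 fell, and 2 and 3 adjusted over the list alone (adjusted p = 0.990, with a median of 0.04 and a mean of -0.03). Of 23 imprinted genes 6 rose and 4 fell, and 6 and 5 adjusted over the list alone (adjusted p = 0.273), led by the growth regulators Plagl1 (1.1998 ± 0.09), Peg10 (1.19 ± 0.09), Cdkn1c (1.75 ± 0.28) and Ndn (0.48 ± 0.06). Of 23 neighbours of HoxB 4 rose and 1 fell by either adjustment (adjusted p = 0.196), with Copz2 (1.14 ± 0.15), Skap1 (1.38 ± 0.29) and Prr15l (2.199 ± 0.50) higher and Sp6 (-0.69 ± 0.19) lower.

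Signs of stress and of RNA yield moved as follows. Among 12 immediate early and heat shock genes 4 rose and 2 fell, and 5 and 2 adjusted over the list alone (adjusted p = 0.158), with Jun (1.199 ± 0.07) and Dnajb1 (0.32 ± 0.06) up and Egr1 (-1.51 ± 0.26) and Atf3 (-0.97 ± 0.14) down. Among 14 hypoxia and glycolysis genes 2 rose and 3 fell by either adjustment (adjusted p = 0.693), with Adm (2.53 ± 0.28) and Pfkfb3 (0.49 ± 0.07) up and Vegfa (-0.40 ± 0.08) and Slc2a3 (-0.70 ± 0.15) down. Mitochondrially encoded genes had a median of -0.94, with 1 of 11, mt-Co2 (-1.13 ± 0.25), past the threshold by either adjustment (adjusted p = 0.00263; adjusted p = 0.512 with an estimated correlation). The InvClone1 pair, with the 144h library low in mitochondrial counts, changed by a median of -3.61 over these genes and the other 4 lines by -0.61 to -0.17. Without that pair the median was -0.41 and 7 of 11 passed by either adjustment, mt-Co2 among them (-0.997 ± 0.25, adjusted p = 0.00597). Pluripotency and germ cell genes had a median of 0.50, with 1 of 12, the epiblast gene Fgf5 (2.28 ± 0.43), past it by either adjustment (adjusted p = 0.0413; adjusted p = 0.410 with an estimated correlation). Histone gene H1f5 rose (1.48 ± 0.37), the only one of 7 over all genes and 1 of 2 adjusted over the list alone (adjusted p = 0.158). None of 18 proliferation genes (adjusted p = 0.990) and none of 3 measured Y-linked genes and Xist (adjusted p = 0.693) passed by either adjustment.

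The count of 2280 was 4831 without the InvClone1 pair, whose 144h library is the one low in mitochondrial counts, and 1366, 1365 and 1413 without the pair of Del, InsDel8to10 or InvDel7to10. With limma on the FPKM values it was 1215, and in the fit of all libraries 1757, of which 1409 were among the 2280. In that fit 33 of the values of named genes lost the threshold and 59 kept their side of it.

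The change of each HoxB gene from 120h to 144h was also compared between lines, as the difference from the change in Del. Hoxb13 in Del changed by -0.92 ± 0.59, and the differences from it were 1.67 ± 1.03 in InsDel8to10, 1.39 ± 0.93 in InvClone1, 0.93 ± 0.99 in Ins and 0.83 ± 0.87 in InvDel7to10. None of the 40 tests passed with edgeR, 0 had an unadjusted p under 0.05 and the lowest adjusted p was 0.994. The fit without a library term also called 0. For the other 9 HoxB genes the differences ran from -0.40 ± 0.42 (Hoxb3 in InvClone1) to 0.54 ± 0.59 (Hoxb1 in Ins).

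InvClone1 was followed from 96h to 168h with 1 ISML_third library per stage, and these values were not tested. Hoxb1 was at 96.0, 27.5, 14.8 and 7.74 CPM at 96h, 120h, 144h and 168h, and Hoxb9 at 74.7, 303, 326 and 314 CPM. Hoxb7 was at 2.35, 8.27, 9.27 and 12.0 CPM. Hoxb13 was highest at 168h, at 0.162 CPM (95% Poisson interval 0.0442 to 0.416), 0.323 (0.130 to 0.666), 0.222 (0.0720 to 0.518) and 0.642 (0.381 to 1.02), where 3 counts in a library correspond to 0.107 to 0.139 CPM.

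TruSeq and ISML libraries were compared as a check of the kit, as the TruSeq_second term against the mean of the ISML_second and ISML_third terms, through the InvClone1 libraries at 120h, 2 of each kit. In this contrast 600 of 17769 genes passed, 462 higher and 138 lower with TruSeq. On each side 1 library was among those that stood apart. TruSeq replicate 2 had counts for 54.8% of the listed genes against 43.4% in TruSeq replicate 3, and the ISML_third library was the deviating replicate 1. The calls can thus not be put down to the kit alone. The most certain calls were pseudogenes, among them Eif5al3-ps (3.97 ± 0.23, adjusted p = 3.36e-06) and Rps7-ps3 (2.21 ± 0.16, 3.32e-05), whose reads can be shared with their parent genes. These were named after their values were seen.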

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

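The tests of the differences between the clones, of the chromosome segments and of the endoderm markers were chosen only after the results were seen, while the splits of the samples were planned. Of 40 groups of 4 or 5 values tested for a member far from the rest, 2 had one, where chance gives about 1 in 20.

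Hoxb7 rose from 120h to 144h by 1.23 on the log2 scale in InvClone1 and by 0.30 to 0.46 in the other 4 lines, so that InvClone1 stood apart. Its 144h value came from replicate 2, the library with 0.0864% mitochondrial counts, and in the fit of all libraries the change in InvClone1 differed from that in Del by 0.21 ± 0.73 (edgeR adjusted p = 0.994). Dcx, the microtubule gene of young neurons, rose by 7.12 in InsDel8to10 and by 4.23 to 4.86 in the other 4 lines.

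The 2071 genes that passed between InvClone2 and InvClone1 differed from replicate 1 of InvClone1, its ISML_third library at 120h, by a median of 0.96, and as a set not from the other libraries of that clone. That agreement is fixed by the choice of the genes, since the fit rests on the library that shares the label. The median difference from the ISML_second library of InvClone1 was -0.0634 of that from the ISML_third library, but it adds the difference of the label to that of the clones, so a lasting difference between the clones cannot be told apart from one between the labels. A trend on transcript length accounted for 0.0754 of the median difference of the called genes, too little to be the whole cause. A bias shared by the ISML_third libraries of this clone may contribute, since in its 144h ISML_third library the same genes were shifted in the same direction by 0.492 of the shift at 120h (0.47 against 0.95). Against the ISML_second libraries of 4 other lines at the same stage the shift was 0.34 and 0.25 in InsDel5to10, -0.02 and 0.43 in InsDel7to10 and 0.02 and -0.003 in InvClone2, all ISML_third, so part of it was not limited to this clone, and -0.48 in the 144h ISML_second library of InvClone1. The share of 0.492 lay between the values that would settle it, and a biological state of these aggregates at that time cannot be told apart from such a bias, since each stage has 1 such library.

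The segments that separated the lines were the Y chromosome, the X beyond 160 Mb and chromosome 3 between 90 and 120 Mb. In all 14 libraries of InsDel7to10, InvClone1, InvClone2 and InvDel7to10 none of Ddx3y, Eif2s3y, Kdm5d and Uty had more than 3 counts. Too few reads are excluded for Ddx3y, Eif2s3y and Uty, since at the Ins level at least 880.1, 323 and 383 counts were expected in each. For Kdm5d the lowest expected count was 2.08, so too few reads are not excluded there. Xist at 0.568 CPM or lower argues against female cells with an inactive X. Loss of the Y chromosome in these lines is a candidate explanation that would give these values. The median of distal X genes stood at least 0.742 higher in both InsDel5to10 libraries than in each of the other ISML_third libraries at 120h, and that of the chromosome 3 segment at least 0.433 higher in both InsDel7to10 libraries than in each of the other 24 libraries, which argues against a batch effect of the library label. The genes moved together, 96% of the distal X genes and 81.5% of those of the chromosome 3 segment being higher in both libraries of the line, so a gain of each segment during the derivation of the lines is a hypothesis that DNA copy number would test.

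Endoderm markers were lower in InsDel7to10 than in InsDel5to10 by a median of -2.15 over the list in log2 CPM. The largest range of that median within a genotype at 120h, in InvClone1, was 1.21 of this difference, but it ran across library labels. Within the genotypes whose libraries are all ISML_third the ranges were 1.84 in InsDel5to10, 1.502 in InsDel7to10 and 1.09 in InvClone2, at most 0.857 of the difference, and the libraries of InsDel7to10 (-2.80 and -1.29) lay below those of InsDel5to10 (-0.82 and 1.03). A cell composition that varies between batches of aggregates thus cannot be told apart from an effect of the genotype with 2 libraries each. The mean of the ISML_second libraries also stood above that of the others at 120h (exact permutation test, two-sided, p = 9.34e-04), with overlap (lowest 1.1795, highest of the others 1.24), but all 4 libraries of this comparison were ISML_third, so the label as such did not differ between them. An effect of the allele of InsDel7to10 stays open and was not tested apart from these.

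Other splits of the samples were counted for 3 comparisons, in the fit of all libraries with a library term for the genotypes and in that of the 10 libraries for the stages. For Ins against Del 1 of 10 splits of the 6 libraries, the real one, gave 1 gene and the highest of the others gave 0, and 10 splits are too few for a share under 0.05. For InvClone1 against Ins 4 of 35 splits gave 3 genes or more, so chance cannot be excluded from this count. The others of the 4 kept the 3 Ins libraries together and added 1 library of InvClone1 to them, and the low counts of the 3 Y-linked genes in all 14 libraries above argue against chance for these genes. The highest, 660 genes, put replicate 4 of InvClone1 with the Ins libraries, against the ISML_third and TruSeq libraries of InvClone1, and thus followed the library label. That count is many times the real 3 and points to a structure of the samples, while a fit of InvClone1 without its TruSeq libraries also gave 3 genes. For the stages 3 of 100 splits drawn gave 2280 genes or more, and the other two, at 3354 genes, parted only the pair of InvClone1 libraries. Since the fit pairs the libraries of a line, only the 16 splits that part all 5 pairs compare with the real one. Of these the real one gave 2280 genes and the highest of the others 0, and 16 splits are too few for a share under 0.05.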

How the results depend on the processing

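The fits without the 6 libraries that stood apart and the crossed pairing were tests chosen only after the results were seen. Of 2470 values of named genes under alternatives, 2010 kept their direction and their side of the threshold, 117 past the threshold in neither fit changed sign, 313 lost the threshold, 13 gained it and 17 others changed sign. The 43 values of Hoxb13 in the comparisons where it passed are not among them: 30 kept the threshold and 13 lost it. The cause was not tested unless stated. Below about 1 CPM depth limits the folds, and with 2 or 3 libraries per group so does replication.

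With no filter the counts were 89 genes for Ins against Del, 841 for InsDel5to10 against Ins, 957 for InsDel7to10 against InsDel5to10, 9 for InvClone1 against Ins and 1562 for the kit. With DESeq2 they were 385 for InsDel5to10 against Ins, 292 for InsDel7to10 against InsDel5to10 and 1229 for the kit. In the kit contrast the median of all genes was 0.03 in the fit reported, 0.16 with DESeq2 and 0.23 with no filter. Without a library term they were 5, 7 and 0 for InsDel5to10 against Ins, InsDel7to10 against InsDel5to10 and the clones. In fits of the compared libraries alone, without a library term, they were 0 for Ins against Del, 633 for InsDel5to10 against Ins (585 of them lower), 4 for InsDel7to10 against InsDel5to10 and 0 for the clones. With limma the stages gave 1215, and in the fit of all libraries 1757, where 33 values of named genes lost the threshold, the most of any alternative for the stages. The planned fit of the kit contrast without a library term was not run, because the contrast is one of that term.

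Hoxb13 lost the threshold for Ins against Del with the compared libraries alone and no library term (-6.21, adjusted p = 0.102, range over all alternatives 2.99e-89 to 0.102). For InsDel7to10 against InsDel5to10 it did so without a library term (-3.04, 0.258), with the compared libraries alone (-3.02, 0.442) and without the 6 libraries and the library term (-3.05, 0.0805), in a range of 3.97e-19 to 0.442. The 8 calls over the HoxB genes were 8 to 10 with the alternatives chosen beforehand (10 without a library term, 2 of them of Hoxb3). They were 14 without the 6 libraries and the library term, all 8 included, 9 of them of Hoxb13 and 5 of Hoxb2, Hoxb3 or Hoxb6, lower in InsDel5to10 or InvClone2. With that setting 21 genes passed for InsDel5to10 against Ins, 26 for InsDel7to10 against InsDel5to10 and 0 for the clones.

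Leaving out 1 library gave 0 to 1 genes for InsDel5to10 against Ins, with Hoxb13 at 7.003 to 7.73 and past the threshold in none of these fits, and 3 to 939 for InsDel7to10 against InsDel5to10, with Hoxb13 at -3.66 to -2.60. It gave 3 to 303 for InvClone1 against Ins (303 without replicate 4 of InvClone1, where the median of all genes moved to -0.15) and 617 to 1898 for the clones. Leaving out a line gave 1365 to 4831 for the stages.

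With an estimated correlation 0 of 6 list calls held for Ins against Del, 0 for InsDel5to10 against Ins, 1 for InsDel7to10 against InsDel5to10, 1 for InvClone1 against Ins, 0 for the clones and 0 for the stages.

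With the replicate block Ins against Del gave 2 genes, and no named gene of that comparison changed its call. The list tests were not run with that block. In the other comparisons the labels likewise give a number and no pairing. Correlations of same-numbered samples were 0.15 and -0.36 for InsDel5to10 and Ins. They were 0.17, 0.40 and 0.06 for InvClone1 and Ins, where replicate 4 of InvClone1 has no partner, and 0.12 and -0.42 for the clones. The block moved the counts to 942, 0 and 0 there (1216 and 246 genes at an unadjusted p under 0.05 for the latter pair). Between InsDel7to10 and InsDel5to10 the correlation was -0.15, the block gave 3 genes and the crossed pairing 4, with Hoxb13 at -3.06 (0.11995) and -3.04 (0.172).

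The 17 values past the threshold in at least 1 fit reversed as follows. Without a library term, between the clones, Cdk5rap3 lay at -0.00535, Nkx3-2 at -0.0924 and Nkx6-2 at -0.75, and with the compared libraries alone Cdk5rap3 at -0.0053 and Nkx3-2 at -0.0909. For InsDel5to10 against Ins, Hoxb2 lay at -1.12 with the compared libraries alone and at -1.15 with the replicate block, and Hoxb6 at -1.26 with the block. Without the 6 libraries and the library term, between the clones, Cdk5rap3 lay at -0.18, Scrn2 at -0.21, Cited1 at -0.10, Notch1 at -0.00738, Nkx3-2 at -0.82, Nkx6-2 at -1.23, Ndn at -0.0545, Mcm2 at -0.0552 and H4c4 at -0.48.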

Other observations

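The tests in this part were chosen only after the results were seen. Beyond HoxB, values of the ISML_third libraries of InvClone1, 1 per stage and all among the 6 that stood apart, were not tested. From 96h to 120h presomitic and tailbud genes were lower by medians of -2.66 and -1.58 on the log2 scale, and somite and endothelial genes higher by 1.54 and 2.17. T was at 162, 40.3, 10.1 and 10.9 CPM at 96h, 120h, 144h and 168h, and the presomitic gene Tbx6 at 205, 10.3, 0.577 and 0.286 CPM. Msgn1 was at 80.9 and 3.42 CPM and then had 0 counts. Sclerotome gene Pax1 had 0 counts at 96h and stood at 34.2, 55.3 and 27.0 CPM afterwards, and the endothelial cadherin gene Cdh5 was at 0.284, 6.79, 13.0 and 16.6 CPM.

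Neural genes had list medians of 0.16, 3.49 and 5.20 at 120h, 144h and 168h against 96h in these libraries. Sox1 was at 0.487, 13.3, 58.3 and 59.1 CPM and Pax6 at 0.731, 3.56, 66.4 and 149.0 CPM. The neuronal genes Elavl3 (0.447, 0.508, 6.83 and 68.7 CPM) and Dcx (0.203, 0.139, 3.50 and 95.7 CPM) were highest at 168h. Posterior Hox genes of the other clusters had medians of 1.41, 4.03 and 5.80 against 96h, with Hoxa10 at 0, 3.60, 13.0 and 28.2 CPM and Hoxc10 at 0.0406, 10.4, 37.6 and 50.2 CPM. Lin28a, which blocks let-7 maturation, was at 1011, 683, 447 and 189.7 CPM. The genes of these paragraphs were chosen after their values were seen.

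At 120h 5 of 22934 genes did not overlap between the 5 libraries of Del and InsDel5to10, the lines high in Hoxb13, and the 13 others, against 5.35 expected by chance. Hoxb13 was 1 of the 4 that were higher, which was fixed in advance because the libraries were grouped by it. The others were Mir196a-1, which lies between HoxB genes on chromosome 11, 96265164 to 96265265 (mm10), with 93 counts against 2, Sim2 with 142 counts against 23, and Kcnf1 with means of 6.91 and 2.26 CPM. Gm19500 was lower, with 3 counts against 38.

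Medians over the genes of a chromosome, relative to the other libraries, ran from -0.46 on the X to 0.15 on chromosome 7 in replicate 2 of InvClone1 at 144h, and from -0.27 on chromosome 17 to 0.20 on the X in replicate 1 of InvClone1 at 120h. In the other 24 libraries the range was at most 0.267. Among 1984 combinations of 248 windows of 10 Mb and 8 lines, the X and chromosome 3 windows named above held the 4 largest shifts shared by all libraries of a line (0.43 or more), and the next was -0.33.

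The Y-linked genes were higher in InsDel5to10 and InsDel8to10 than the mean of Ins and Del, by ratios of 1.49 to 1.93 for the 4 genes in InsDel5to10 and of 1.54 to 3.27 in InsDel8to10, where the highest was Kdm5d, a gene with few counts.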
